A study of Mus musculus with 4 samples.

How the data were processed

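RNA from FACS-sorted GFP-positive cells of mouse back skin at postnatal day 49 was compared between total GFP-positive cells and α6 integrin-high, CD34-high bulge basal cells, with 2 arrays per group. Per the labels' protocols, 200 ng of RNA was reverse transcribed and amplified with oligo-dT T7 priming, and biotinylated cRNA was hybridised to Affymetrix arrays. Groups were taken from sample titles, since the cell type label is identical for all 4 samples while the title and population labels separate them. The deposited table holds summarised probe set intensity on a linear scale, from 0.0546 to 40835, with a mean after trimming 2% at each end of 500.0 on every array. Array medians were 145.01, 123.6, 128.8 and 126.7. The submitters' processing notes name GCOS, R 2.15.1, affy 1.36 and RMA with no role or order. A common trimmed mean with unequal quartiles is a property of MAS 5.0 style scaling and not of RMA output. The values therefore argue against RMA as their source, and no label says which tool made them. The design assumed log2 values and provided for other scales, and log2 was taken of the deposited intensity before testing.

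Probe sets were named through the platform annotation, with symbols updated by Entrez ID from a RefSeq gene table of GRCm38.p6 used for names and gene spans alone. Of 22690 probe sets, 64 were controls, 20380 had 1 symbol, 691 had several and 1555 had none, and 20351 of those with 1 symbol were matched. Each gene was represented by the probe set with the highest mean over the 4 arrays, giving 12393 genes, of which 4956 had more than 1 probe set. All probe sets went 1 way for 43 of the 55 named genes with several, and for 39 of the 43 with several above background on at least 1 array. No coordinates are given. Controls and probe sets with no or several symbols were left out of the gene tests.

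The file carries no detection flags. A background level was set at the 95th percentile of the values of 64 olfactory, vomeronasal and taste receptor genes, at a log2 signal of 7.18 (signal 144.8). A gene below it on both arrays of a group has only a bound there, and the ratio of the brighter group's mean to the higher of the background level and the dim group's own level is given as at least N-fold. The same ratio is given for called genes below it on 1 array of the dimmer group. These bounds concern the background level alone and carry no sampling error, so the interval of a fit can reach lower folds. No fold is given where both groups were below it. At least 1 group mean lay above it for 7322 genes, 59.1%.

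The principal test was limma 3.58.1 (R 4.3.3), lmFit and eBayes on group alone, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists, 29 with 757 entries of which 678 were measured, were drawn from general knowledge of skin biology and tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The test, the lists, the rule for named genes and the other settings to try were fixed before the data were examined. The rule named the sorting genes Cd34, Itga6 and Krt14, the 12 largest rises and falls among called genes without overlap of the groups, and up to 4 called members per list in the commoner direction and 2 in the other, or the 2 brightest where none was called. Because the principal test called none, the rule was applied to the trended fit as well, a step chosen after seeing that result. The settings fixed in this way were array centring, quantile normalization, a robust or trended variance model, 2 filters on dim genes, other probe set rules, a test against a 1.5-fold change, a threshold of 0.01, a replicate block, each array left out, and camera on ranks or with an estimated correlation and fry for lists. A log2 of signal plus 32 and combinations with the block were added after seeing the data.

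The fits were tested on simulated data with 12393 genes over 20 draws, with 200 genes changed per draw. For this comparison the principal fit recovered 0.149% of genes changed by a log2 of 1, 3.51% at 2 and 84.2% at 4, with 3.89% of calls false. The trended fit recovered 2.31%, 33.4% and 90.0%, with 6.03% of calls false, above the nominal 5% of its threshold. The simulated genes varied independently, with a spread set by mean level alone and equal in both groups, a setting that favours the trended fit. On these arrays replicate differences had an SD of 0.527 in the total group and 0.903 in the bulge group, for genes above background. They correlated between the groups at r = 0.602. The recovery and false call rates may therefore not hold for these arrays.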

Results

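Gene expression was measured on 4 Affymetrix mouse arrays hybridised with RNA from sorted cells of back skin. The mice expressed a fusion of GFP and actin under the keratin 14 promoter, which is active in basal keratinocytes, and were at postnatal day 49, when hair follicles rest in telogen. The 2 arrays of the total group held all living GFP-positive cells, and the 2 arrays of the bulge group held GFP-positive cells with high surface levels of α6 integrin and CD34, a gate for basal cells of the hair follicle bulge. The total sort was not depleted of bulge cells, so a difference between the groups compares bulge basal cells with a mixture that contains them. The deposited signals covered 22690 probe sets per array, and 12393 genes with a symbol of their own were tested. The number of arrays, 2 per group, limits the precision. No label says that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Every difference is the bulge group minus the total group on the log2 scale, and an n of 2 arrays per group applies throughout.

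Cd34, the surface marker of the gate, was 15.1-fold higher in the bulge group, with log2 signals of 9.94 ± 0.31 (SD, n = 2) in the total group and 13.86 ± 0.11 (SD, n = 2) in the bulge group. Itga6, which encodes the α6 integrin used in the same gate, was not higher: its log2 signals were 12.46 and 11.77 on the total arrays and 11.69 and 10.73 on the bulge arrays, a difference of -0.91 (95% interval -2.22 to 0.41) that did not pass the test, and its other probe set gave -1.29 with overlapping groups. Krt14, whose promoter drives the reporter, had a difference of -0.30 and overlapping groups, and its other 2 probe sets gave -0.65 and -2.42. Cd34 and Itga6 selected the cells and are given as a check of the labels.

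The series set out to find the genes that distinguish bulge basal cells in telogen from the whole epidermis. The bulge stem cell markers Dkk3 and Ltbp2 lay 19.6-fold and at least 17.3-fold higher in the bulge group and the collagen gene Col6a2 13.4-fold, although other probe sets gave smaller log2 differences of 3.27 for Dkk3 and 2.19 for Col6a2, while Krt79 lay 11.0-fold lower, Krt1 9.94-fold lower and the myeloid receptor gene Csf1r 12.5-fold lower. In the limma fit planned as the principal test, no gene passed an adjusted p of 0.05 (0 higher, 0 lower). The smallest adjusted p was 0.0729, and 1297 genes had an unadjusted p under 0.05, of which 642 were higher and 655 lower. The limma fit with an intensity trend, fixed as another test before the data were examined, called 69 genes higher and 65 lower. For the 65 of these 134 that were above background on all 4 arrays, the log2 difference was at least 2.07 in size. Another 17 were below background on 1 of the 2 arrays of the dimmer group, and their folds are given as lower bounds. Such bounds hold for the background level and leave out sampling error. Of the other 52, 46 have only a lower bound, which was under 2-fold for 13, and 6 were below background in both groups. A filter on dim genes, likewise fixed, called 107 higher and 122 lower, and 128 of the 134 genes of the trended fit were among them. The verbs rose and fell below refer to the trended fit for single genes, and the choice to describe its genes was made after the principal test had returned none. The trended fit lost all its calls without either total array, and their number grew without either bulge array. In such fits the spread came from the intact pair alone. Replicate differences varied more in the bulge group (SD 0.903) than in the total group (SD 0.527), for genes above background. Groups did not overlap for 4769 genes, 38.5% of those tested, where chance gives 33.3%. The chance levels here and below assume 4 exchangeable arrays. Same-numbered arrays deviated together, as described below, so these levels may not hold here.

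**Figure D1:**
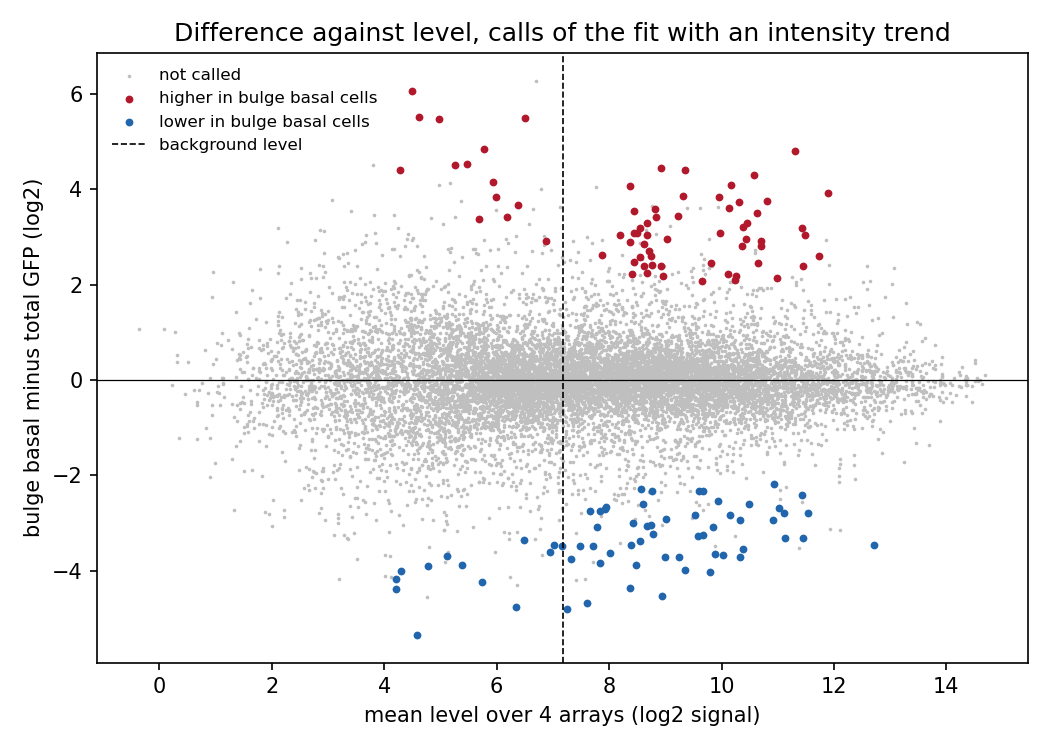
Each point is 1 of 12393 genes, with the mean log2 signal over the 4 arrays on the horizontal axis and the bulge minus total log2 difference on the vertical axis. Red and blue points are the 69 higher and 65 lower genes called by the fit with an intensity trend, and the dashed line marks the background level of 7.18.

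The rule named 12 rises by their fitted differences, which give no order among genes below background in a group. S100a4, a calcium-binding protein gene, rose 28.1-fold from a signal of 479 to 13433, with a log2 difference of 4.81 ± 0.69 (SE) and an adjusted p of 0.0442 in the trended limma fit. Dkk3, a secreted protein of the Dickkopf family, rose from 344 to 6743, a difference of 4.29 ± 0.34 (SE) with an adjusted p of 0.0297. Ltbp2, a latent TGF-β binding protein above background on 1 of 2 total arrays, rose at least 17.3-fold. Trpv4, a calcium-permeable cation channel gene, rose at least 4.21-fold, Pcolce2, a procollagen processing enhancer, at least 15.7-fold, and Bambi, a decoy receptor for BMP and TGF-β ligands, at least 2.02-fold. Slc22a22, Map6, Gdf10, Irx4 and Gfra1 were also below the background level in the total group, and their rises are bounded at 1.27, 1.15, 1.44, 1.47 and 1.26-fold or more. Armh4 passed the test but was below background in both groups, and no fold is given for it.

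The 12 falls were named in the same way. Tnfrsf19, a TNF receptor family gene also known as Troy, fell at least 16.2-fold, from a total signal of 2354. The transcription factor gene Sox6 fell at least 5.54-fold, the retinaldehyde dehydrogenase gene Aldh1a1 at least 2.92-fold and the adenylate cyclase gene Adcy7 at least 6.85-fold, with the other 2 Adcy7 probe sets below background on all 4 arrays. Akr1c18, a hydroxysteroid dehydrogenase gene above background on 1 of 2 bulge arrays, fell at least 15.6-fold and Clca3a1 fell 15.8-fold. The other Tnfrsf19 probe set above background on the total arrays gave -2.37. The other falls included leukocyte genes: the lysosomal protease gene Ctss fell at least 10.4-fold, Itgae, which encodes the αE integrin of intraepithelial lymphocytes, at least 1.60-fold, and the T cell receptor gamma segment Trgv1 at least 1.05-fold. Ahrr, Lcn2 and Cdc25c passed the test but lay below background in both groups.

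Bulge stem cell markers were higher as a list. Of 32 measured genes, 9 rose and 23 did not pass in the trended fit, and 21 were higher and 0 lower when p-values of the principal fit were adjusted over the list alone, against 0 over all genes. Lgr5, a receptor for R-spondins, rose 9.77-fold and the LIM homeobox gene Lhx2 rose 7.06-fold, alongside Dkk3 and Ltbp2. Krt15, the brightest member, had signals of 20635 and 26409 and a difference of 0.36 that did not pass, and Postn had 1.22. The list median was 2.02 (quartiles 1.04 and 2.74), and camera with a preset correlation gave an adjusted p of 1.82e-20 over 29 lists. For this list the adjusted p = 0.353 with an estimated correlation, and none of the 10 lists that passed with the preset correlation was called with an estimated one. With each value raised to at least the background level, the median was 1.94 for this list, 0.48 for matrix, 0.32 for actin, 0.02 for Hedgehog and 0 for BMP and TGF-β genes. On the same scale it was -0.995 for cell cycle, -0.72 for infundibulum and isthmus, -0.60 for interferon response, -0.71 for Langerhans cell and macrophage and -0.35 for T cell genes.

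**Figure D2:**
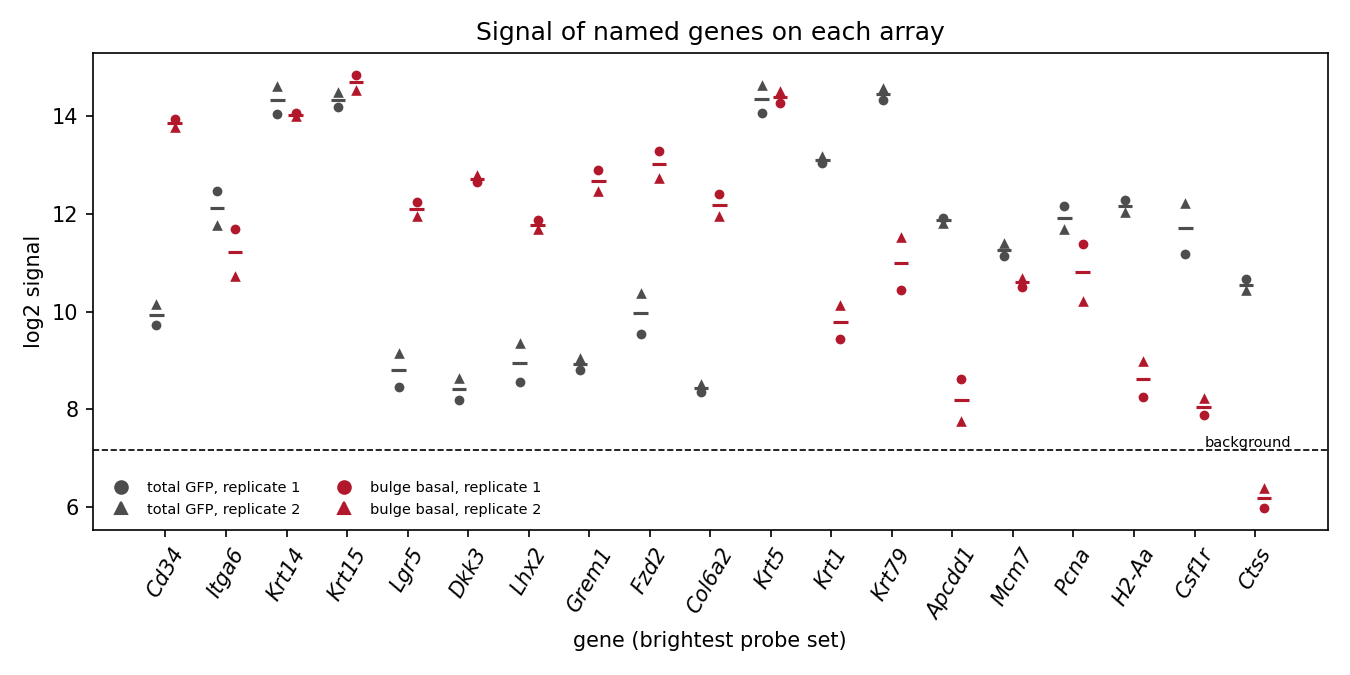
The log2 signal of 19 genes is shown on each array, with circles for replicate 1, triangles for replicate 2 and bars for the group means. The bulge arrays lie above the total arrays for Cd34, Lgr5, Dkk3, Lhx2, Grem1, Fzd2 and Col6a2, and below them for Krt1, Krt79, Apcdd1, H2-Aa, Csf1r and Ctss.

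Genes of BMP and TGF-β signalling were higher as a list. The list shares Fst, Ltbp1 and Ltbp2 with the bulge stem cell markers, so the 2 results are not independent. Of 38 measured genes, 5 rose, 0 fell and 33 did not pass, with 10 higher and 1 lower adjusted over the list alone, and the list median was 0.31 with a camera adjusted p of 4.89e-04 (adjusted p = 0.782 with an estimated correlation). Grem1, a secreted BMP antagonist, rose 13.5-fold from 486 to 6556, and the follistatin-like gene Fstl1, above background on 1 of 2 total arrays, rose at least 14.3-fold. Fst, another antagonist, had a difference of 2.08 that did not pass. The ligand gene Bmp4 went the other way without passing. Its difference was -4.17, bounded at 5.58-fold lower or more, since it was below background in the bulge group. Hedgehog pathway genes were also higher, with a median of 0.41 over 12 genes and an adjusted p of 0.0159 (adjusted p = 0.782 with an estimated correlation). Gli2, a transcriptional effector of the pathway, rose at least 7.81-fold and was the only 1 of the 12 that passed, with 2 higher adjusted over the list alone. Without bulge replicate 1 the adjusted p was 0.196 for the BMP and TGF-β list and 0.180 for the Hedgehog list, and without total replicate 2 the latter was 0.0521.

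Wnt pathway genes moved in both directions. Fzd2, a Wnt receptor, rose 8.27-fold and Dkk3 and Lgr5 rose as above, while Apcdd1, a membrane-bound Wnt inhibitor, fell 12.8-fold. The list of 39 genes had 3 that rose, 1 that fell and 35 that did not pass, with 5 higher and 4 lower adjusted over the list alone, a median of -0.21 and an adjusted p of 0.747. In the FGF and EGF family, Fgf1, above background on 1 of 2 total arrays, rose at least 7.14-fold (its other probe set gave a log2 difference of 1.89) and the EGF family ligand gene Epgn fell 9.56-fold, with 22 of 25 members not passing, 3 higher and 1 lower adjusted over the list alone and an adjusted p of 0.787; the median was -0.02, while the mean was 0.07 and camera's direction was upward. Fgfr1 rose 4.75-fold, with its other probe set below background on all 4 arrays. Notch3, a Notch receptor, fell 7.13-fold (its other probe set gave -1.30) as the only member of 20 Notch pathway genes to pass (adjusted p = 0.527 for the list, 1 lower adjusted over the list alone).

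Extracellular matrix genes were higher on balance. Their list shares Col18a1, Npnt, Postn and Tnc with the bulge stem cell markers, so it is no independent result. Of 44 measured collagens and matrix genes, 6 rose, 1 fell and 37 did not pass, with 12 higher and 3 lower adjusted over the list alone. Col6a2 rose 13.4-fold, Col5a2 10.9-fold and the matricellular protein gene Sparc 6.07-fold, while Efemp1, a fibulin gene, fell 13.0-fold. The median was 0.74 with an adjusted p of 1.00e-05 (adjusted p = 0.782 with an estimated correlation). Markers of fibroblasts and dermal papilla, tested because they also express matrix genes, did not pass (adjusted p of 0.787, 1 higher adjusted over the list alone), with 3 of 16 members above background in either group. Their median was -0.03, their mean 0.28 and camera's direction upward, and the median of these 3 members was 0.99. Col1a2 had a difference of 2.96 that did not pass. The list of actin cytoskeleton and focal adhesion genes had a median of 0.48 over 31 genes and an adjusted p of 8.18e-04 (adjusted p = 0.353 with an estimated correlation), with 15 genes higher without overlap of the groups and 1 lower, where chance gives 5.17 each way. Its only called member went against that direction: Vim, an intermediate filament gene, fell at least 4.14-fold, and it was also the only member lower adjusted over the list alone, with 0 higher.

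**Figure D3:**
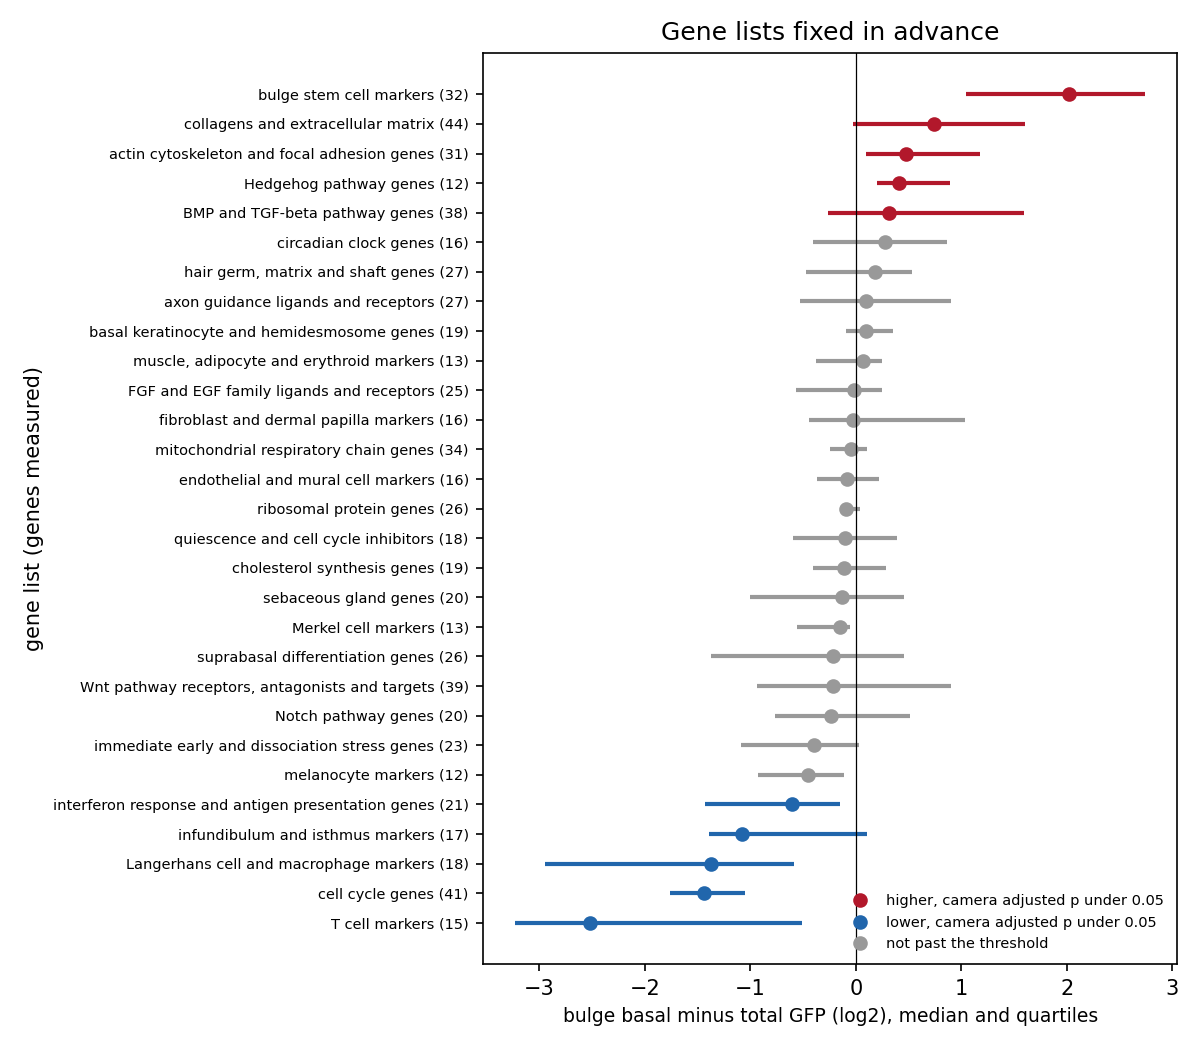
Points are the median bulge minus total log2 difference of each of the 29 gene lists and bars its quartiles, with the number of measured genes in brackets. Of the 10 coloured lists, 5 are higher (red) and 5 lower (blue). Values below background enter as measured, so the median of -2.52 for T cell markers becomes -0.35 with values raised to the background level.

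Genes of other epidermal compartments were lower or mixed. Krt79, a keratin of the infundibulum and sebaceous duct, fell 11.0-fold from a signal of 22270 and was the only infundibulum and isthmus marker of 17 to pass. Adjusted over the list alone, 2 were higher and 3 lower; the median was -1.07 and the adjusted p 0.0283 (adjusted p = 0.910 with an estimated correlation). Without bulge replicate 1 the adjusted p of that list was 0.414. Among 26 suprabasal genes, Krt1, a keratin of differentiating layers, fell 9.94-fold and Notch3 fell as above, with 3 lower and 0 higher adjusted over the list alone. The suprabasal list did not pass with all arrays (median -0.21, adjusted p of 0.191). It was lower with an adjusted p of 0.0166 without total replicate 1 and 6.18e-04 without bulge replicate 2, and camera's direction turned upward without bulge replicate 1 (adjusted p of 0.816). These fits used the preset correlation alone, and with all arrays the list had an adjusted p = 0.937 with an estimated correlation. Krt10 and Dmkn had differences of -0.47 and 0.27. Basal keratinocyte genes did not pass either (0 of 19 called, 0 higher and 0 lower adjusted over the list alone, adjusted p of 0.747), with a median of 0.09, a mean of -0.06 and camera's direction upward. Krt5 had a difference of 0.05 at signals of 20832 and 21505. Sebaceous gland genes had a median of -0.13 over 20 members and an adjusted p of 0.268, with 0 higher and 2 lower adjusted over the list alone, and were lower with an adjusted p of 0.0125 without bulge replicate 2 at the preset correlation (with all arrays, adjusted p = 0.937 with an estimated correlation).

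Cell cycle genes were lower in the bulge group. Of 41 measured genes, 38 had both bulge arrays below both total arrays and 0 the reverse, where chance gives 6.83 each way. None of the 41 passed over all genes, and 15 were lower and 0 higher adjusted over the list alone. Mcm7, a subunit of the replicative helicase, had a difference of -0.67 and Pcna, the polymerase clamp, -1.12. The list median was -1.44 (quartiles -1.76 and -1.05), and camera gave an adjusted p of 2.65e-20 (adjusted p = 0.353 with an estimated correlation). Cell cycle inhibitors and quiescence genes did not pass, with a median of -0.10 over 18 members and 1 lower adjusted over the list alone. Leukocyte markers, described next, were lower on the same arrays.

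Markers of leukocytes were lower in the bulge group. Of 15 measured T cell markers, the pan-leukocyte phosphatase gene Ptprc fell at least 2.98-fold and 14 did not pass, with 9 lower and 0 higher adjusted over the list alone, a median of -2.52 and an adjusted p of 2.53e-07 (adjusted p = 0.353 with an estimated correlation). Of 18 Langerhans cell and macrophage markers, 4 fell, 1 rose and 13 did not pass, with 9 lower and 1 higher adjusted over the list alone and an adjusted p of 1.62e-07 (adjusted p = 0.353 with an estimated correlation). The MHC class II genes H2-Aa and H2-Ab1, the latter above background on 1 of 2 bulge arrays, fell 11.6-fold and at least 7.49-fold. Csf1r fell 12.5-fold from a signal of 3335, with -3.95 for another of its probe sets and -0.51 for the remaining one, which was near background on the total arrays. Mfge8, a secreted phosphatidylserine-binding protein gene made by many cell types, rose 5.44-fold. Interferon response and antigen presentation genes were lower on the same arrays, with a median of -0.60 over 21 genes, 2 lower adjusted over the list alone and an adjusted p of 0.00201 (adjusted p = 0.353 with an estimated correlation). Their brightest member B2m had a difference of -0.87.

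Several groups did not pass the threshold with all arrays. Hair germ, matrix and shaft genes had a median of 0.18 over 27 members and 1 that rose, the homeobox gene Hoxc13, at least 3.99-fold, with 1 higher and 1 lower adjusted over the list alone. Immediate early genes had a median of -0.39 and an adjusted p of 0.15, with 0 higher and 1 lower adjusted over the list alone; Egr2 fell 9.62-fold, while its other probe set gave a log2 difference of -1.81, and Egr1 had -1.35 without passing. Medians were -0.10 for 26 ribosomal protein genes, -0.05 for 34 respiratory chain genes, -0.12 for 19 cholesterol synthesis genes, 0.28 for 16 clock genes and 0.10 for 27 axon guidance genes, and 0 members of these 5 lists passed, with 0 adjusted over the list alone. Some of these lists passed with an array left out, in fits run at the preset correlation alone, while with all arrays each had an adjusted p = 0.937 or 0.954 with an estimated correlation. Immediate early genes were lower without total replicate 1 (adjusted p of 5.13e-07), and ribosomal protein genes were lower without total replicate 1 (0.0432) and without bulge replicate 2 (6.63e-04). Without bulge replicate 2, respiratory chain (0.00491) and cholesterol synthesis genes (0.0165) were lower and clock genes higher (0.0384). Camera's direction for each of these 5 lists turned in at least 1 other such fit. Melanocyte markers had a median of -0.46 over 12 genes and an adjusted p of 0.191, 0 members adjusted over the list alone, Mitf at 2.67 and Dct at -1.22, neither of which passed. For Merkel cell markers the median was -0.15 and the mean 0.01, with camera's direction downward, and the neuropeptide gene Cck, above background on 1 of 2 total arrays, rose at least 8.85-fold, the only 1 higher adjusted over the list alone. Medians were -0.08 for 16 endothelial and mural cell markers and 0.07 for 13 muscle, adipocyte and erythroid markers, most of which lay below background, with 0 called adjusted over the list alone.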

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

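All tests in this part were chosen after the results were seen. Probe sets without a single gene symbol stayed out of the gene comparison, 2246 of them in all. In a limma fit with an intensity trend over all probe sets, 8 of them passed an adjusted p of 0.05, which is a signal in data outside the main comparison. The only 1 that rose was below background in the total group, so its fitted difference of 5.08 (adjusted p of 0.0449, higher on 2 of 2 bulge arrays) is bounded at 2.52-fold or more, and the annotation lists 2 symbols for it. The other 7 fell. Of these, 3 were below background in the bulge group and fell at least 13.9-fold, 11.4-fold and 6.79-fold, and the 4 measured in both groups had differences from -4.42 to -2.74.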

How the results depend on the processing

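The combinations with the replicate block, log2 of signal plus 32 and every alternative of the trended fit were chosen after the data were seen. The principal count of 0 higher and 0 lower held under centring, quantile normalization, a robust fit, the 3 other probe set rules, a 1.5-fold treat test, an adjusted p of 0.01 and each array left out. It became 107 higher and 122 lower with the background filter (7322 genes tested), 64 and 62 with the dimmer part of the genes left out, 69 and 65 with an intensity trend, and 18 and 19 with log2 of signal plus 32. A limit of 2-fold on fitted differences left these counts as they were, but it is no bound for genes below background; why the calls appear was not tested. Counts of the trended fit were 21 and 22 after quantile normalization, 38 and 48 in a robust fit, 34 and 39 with log2 of signal plus 32, 99 and 104 with the background filter, and 0 and 0 at an adjusted p of 0.01. With each array left out they ranged from 0 to 171 higher and 0 to 217 lower, the lone array of a group being assumed to vary like the others; the cause was not tested. The samples share only a number. The replicate 2 minus 1 differences of the 2 groups correlated across genes at r = 0.295 (0.602 for 6849 genes above background), and genes are not independent replicates. The replicate block gave 0 and 0 alone, 559 and 556 with the filter, and 467 and 450 with the trend. With block and filter the smallest adjusted p of the limma fit was 3.05e-57. From 4 arrays so small a value rests on variance pooled across genes, so the counts with the filter are no evidence for pairing. The 5 higher and 5 lower lists became 0 and 0 with an estimated correlation and 0 and 0 by fry (smallest adjusted p 0.0810), and 3 to 6 higher and 4 to 10 lower with an array left out; the cause was not tested. Among called genes, Adcy7 gave 1.28 with 1 of its 2 other probe sets and -2.21 with the other, and Fgfr1 gave -0.18 with its other probe set or without cross-hybridising ones; these 3 probe sets were below background on all 4 arrays and carry no direction. Genes called in no fit changed sign 51 times in 23 genes, and lists not past the threshold 28 times in 16. Signal over background limits folds for 52 of the 134 genes of the trended fit, which were below background on both arrays of the dimmer group. It also limits folds for another 17, which were below background on 1 array of that group.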

Other observations

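The tests in this part were chosen after the results were seen, except those of scaling and of gene length as a bias for the replicate pattern, which were written before, and the leukocyte test replaced one void because it had chosen markers by their total signal. Genes named in this paragraph outside the rule were chosen after their values were seen, and the verbs refer to the trended limma fit. Il31ra, a subunit of the interleukin 31 receptor, rose 17.1-fold from a signal of 277 to 4746, and Il33, an epithelial alarmin, fell 13.2-fold from 4649 to 353. The aryl hydrocarbon receptor gene Ahr fell 6.86-fold from 7832 to 1142, with its other probe set below background on all 4 arrays. Kcnk2, a potassium channel gene, rose 11.4-fold, Duoxa1, a maturation factor of dual oxidases, rose 9.14-fold, and Smoc2, a matricellular protein gene, fell 7.16-fold, with a log2 difference of -1.77 for its other probe set, which was below background in the bulge group.

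The homeobox genes Hoxd8, Hoxd9 and Hoxc13 rose, by 6.09-fold, at least 1.77-fold and at least 3.99-fold. In a scan of 23 symbol families with camera, the 31 Hox genes were higher with an adjusted p of 0.0109, a median of 0.50 and 14 genes higher against 4 lower without overlap, where chance gives 5.17 each way. The family's adjusted p = 0.675 with an estimated correlation, and the scan includes the 3 called genes, so it does not settle whether the family shifted. Collagen and Frizzled genes passed upward and Sox, interleukin and MHC class II genes downward, 6 families in all, and none with an estimated correlation (adjusted p = 0.601 to 0.675 with an estimated correlation). Of the 31 Hox genes, 15 were above background in either group.

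Of the 33 T cell, Langerhans cell and macrophage markers, 22 had both bulge arrays below both total arrays and 3 the reverse, where chance gives 17% each way. The brightest of them in the total group, H2-Aa and Csf1r, had signals of 4563 and 3335 there. The median difference was -0.0066 over 6849 genes above background, so the groups showed no uniform shift. Every array already had a trimmed mean of 500, which holds this median near 0. The value therefore does not decide on array scaling as a cause. Fewer leukocytes in the bulge sort, cells that the GFP gate should exclude from both sorts, cannot be told apart from lower expression by bulge keratinocytes, which was not tested. Of 73 leukocyte genes outside the lists, 31 were lower and 2 higher without overlap. The set was written after at least its member Cytip had been seen to be called lower. Only 8 had a mean over the 4 arrays above background, and 4 of those (50.0%) were lower. That mean can leave out genes with 1 group mean alone above background, such as Klrd1 (signal 367 to 18.6) and Syk (104 to 178). The 50.0% therefore does not decide whether leukocytes were fewer. Arhgdib went from a signal of 952 to 89.4 in that set and Ptpn6 from 925 to 1006, and how many of these genes keratinocytes express was not examined.

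Arrays with the same replicate number deviated together, with r = 0.602 between the groups across 6849 genes above background and 0.295 across all genes, which are not independent replicates. In signal above background, the 2 bulge arrays correlated at 0.855, no closer than each did with its same-numbered total array (0.861 and 0.859). Across all genes these values were 0.924, 0.923 and 0.921. The 2 total arrays correlated more closely with each other than with either bulge array. Unequal intensity distributions are argued against by an r of 0.624 between the groups' replicate differences after quantile normalization. Replicate 2 minus 1 fell with gene span in both groups (Spearman rho -0.326 and -0.414), consistent with a length bias, but removing that trend left r at 0.545, so span is argued against as the whole cause. Whether RNA quality underlies the bias stays open, since the 3' minus 5' log2 difference of the Actb controls was 2.36 and 2.99 on total replicates 1 and 2 and 2.50 and 3.45 on the bulge ones, and that of Gapdh 3.61 and 4.09, and 3.98 and 3.37. More differentiated cells in the replicate 2 sorts cannot be told apart from the rest, since the suprabasal median of replicate 2 minus 1 was 0.22 in the total group and 0.74 in the bulge group. In the bulge group such medians were 0.92 for infundibulum and isthmus, 0.45 for cell cycle and -0.35 for bulge stem cell genes. The total group gave -0.16, -0.21 and -0.05. Medians of the 10 lists that passed shifted toward the total group in bulge replicate 2, except interferon response (-0.18). Ribosomal protein genes, which did not pass, gave 0.95 in the bulge and 0.61 in the total group. A share of non-bulge cells in bulge replicate 2 was not tested.

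Itga6 was not higher in the α6-high sort. Both bulge arrays lay below both total arrays for the probe set used, and the other probe set was lower in the bulge group within each replicate number. A faulty probe set still cannot be told apart from a true lack of a rise, since that other probe set's -1.29 has a 95% interval from -3.61 to 1.03. The criterion of an interval on 1 side of 0 was set after this value was seen. Swapped labels are argued against by Cd34, whose lowest bulge array lay 3.62 above the highest total array. Differences between surface protein and transcript levels remain open as an untested explanation.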
